A study of Mus musculus with 6 samples.

How the data were processed

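RNA from 6 samples of cultured mouse cells, 2 each of SSC, iSSC and mSSC, was measured on Affymetrix microarrays. Per the labels, total RNA was extracted with Trizol and 10 µg was amplified and biotin-labelled with NuGEN Ovation kits. The clumps came from early (0 to 1) and middle (9 to 10) passages, and which array came from which passage is not given in the sources used here. The deposited values are log2 signals made by the authors with RMA, which subtracts background, quantile-normalizes the arrays and summarises the probes of a probe set. RMA is named in the submitters' processing notes, and its version is not given in the sources used here. The array medians of the deposited log2 values lay between 5.83 and 5.93, and no further normalization was applied.

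Of 45101 probe sets 34958 had exactly 1 gene symbol, 932 had several and 9211 were not named in the probe table used here. Symbols were matched by gene identifier to the RefSeq gene table of the mouse assembly GRCm38.p6, which matched 34754 probe sets and updated 0 symbols. Of this table only names and gene spans were used. Where a gene had several probe sets, as 9012 genes did, the one with the highest mean over all 6 arrays stood for it, which left 18194 genes. There was no filter on low values, and 0 columns of the deposited table were left out. Probe sets with no single symbol were tested apart from the genes. The genes H19 and T, which the plan named, had no value in the table.

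Groups were compared with limma 3.58.1 in R 4.3.3, by a group means model over all 6 arrays with moderated variances, 2-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The 3 comparisons were mSSC against SSC, iSSC against SSC and mSSC against iSSC. A gene was counted as apart in iSSC when it was called in the same direction against both other groups. The position of iSSC is the median, over the genes called between mSSC and SSC, of the iSSC minus SSC difference divided by the mSSC minus SSC difference, and has no p-value. Gene lists with at least 5 measured members, 38 in all, were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. No call of a list in the 3 comparisons held with an estimated correlation. That setting is tested on the 3 residual degrees of freedom of the fit, and the preset on far more. A call lost there does not by itself show that the genes of a list move together. For core pluripotency in mSSC against SSC the estimated correlation was 0.012, near the preset. Even so, the unadjusted p of camera went from 8.3e-18 to 0.0034. Over the 38 lists the median estimated correlation was 0.14, above the preset. It was 0.68 for fibroblast, 0.50 for macrophage and 0.47 for glycolysis genes, but 0.0012 for Sertoli cell genes. Where the estimate is far above the preset, the p of camera at the preset may be much too small. Fry, which tests whether the genes of a list move on balance in 1 direction and compares them with no other genes, was run beside camera. For each list the called members were counted over all genes and adjusted over the list alone.

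Groups, comparisons, gene lists, the rule for named genes and the other settings to try were fixed before the data were examined. The rule names, per comparison, the 8 genes with the largest increase and the 8 with the largest decrease among called genes whose groups do not overlap. It adds the 4 members with the smallest p of each list described and a fixed panel of pluripotency, germ line, adhesion, stromal and imprinted genes. Of the genes apart in iSSC it names 6 in each direction. Genes outside this rule are said to have been chosen after their values were seen. Not every gene that the rule allows is named in the text.

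These settings were a term for the replicate number, a filter on dim genes, fits on 4 arrays, other variance models, an unmoderated test, other scalings, other ways to combine probe sets, minimum changes of 2-fold and 1.2-fold, lists without shared members, and leaving out each array in turn. Removal of a trend on gene length, and quantile normalization before the list tests, were added after seeing the data. Where an array is left out, the lone array of its group is assumed to vary like the other groups. The calls were tested on simulated data in 20 runs, each with 200 changed genes, in which 2-fold and 4-fold changes were mixed. Of 4-fold changes 36.0% were found in iSSC against SSC, 34.4% in mSSC against SSC and 33.4% in mSSC against iSSC, with 3.33%, 3.49% and 4.13% of calls false. Of 2-fold changes 0.25% were found in each. In the data mSSC against SSC had 3425 calls and mSSC against iSSC 3117, far more than the genes changed in a simulation. Their smallest called changes were 0.72 and 0.74 in size, so the simulated rates do not carry over to these comparisons. The simulated genes were also independent of each other and varied alike in every group. In the data the median SD of a gene between replicates was 0.247 in SSC and 0.139 in iSSC. The false share of 3.33% therefore need not hold for iSSC against SSC either. Figures were drawn with matplotlib 3.10.9, and tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.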

Results

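Gene expression was measured in 3 kinds of cultured mouse spermatogonial stem cell, the testis cells that maintain sperm production. The cultures came from male ICR mice aged 3 to 5 days. Clumps of stem cells were kept on feeder layers of growth-arrested embryonic fibroblasts, and the colonies were picked by shape. The labels call the kinds unipotent germ-line stem cells (SSC), an intermediate state (iSSC) and a multipotent state (mSSC). Each kind was profiled on 2 arrays, so every group mean below rests on n = 2 and the number of arrays limits the precision. The labels do not say whether the replicates of a kind are separate cultures or animals, so the p-values measure only the spread between these samples. Each array held 45101 probe sets, from which 18194 genes were taken. The median log2 value of an array lay between 5.83 and 5.93. Changes are log2 differences of group means ± SE unless a fold is given. The SE draws on the spread within all 3 groups, so it can be smaller than the spread of the groups compared. The lower quartile of an array lay between 4.23 and 4.38, and a gene below it in 1 group is near background there, so that its difference depends on the background and no fold is given.

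The mSSC arrays stood apart from the other 4. Across genes, which are not independent replicates, Pearson's r of an mSSC array with an SSC or iSSC array lay between 0.884 and 0.919. SSC and iSSC arrays were closer to each other, with r from 0.949 to 0.970. Within a kind, r was 0.972 for SSC, 0.990 for iSSC and 0.972 for mSSC. Component 1 of a principal component analysis held 61.1% of the variance and separated mSSC from the rest, and component 2 held 19.4%. The median SD of a gene between the 2 arrays was 0.247 in SSC, 0.139 in iSSC and 0.206 in mSSC. More than 2-fold differences between replicates were seen for 1864 genes in SSC, 295 in iSSC and 1403 in mSSC. In SSC replicate 1 the signal of the 3' end of the beta-actin control exceeded that of the 5' end by 0.89, against 0.12 to 0.61 in the other 5 arrays. The excess was also largest in this array for the transferrin receptor (2.56, against 1.12 to 2.07), pyruvate carboxylase (2.74, against 0.88 to 1.32) and Gapdh (0.25, against -0.35 to -0.10), but not for 18S rRNA (2.23, against 0.41 to 2.42).

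**Figure D1:**
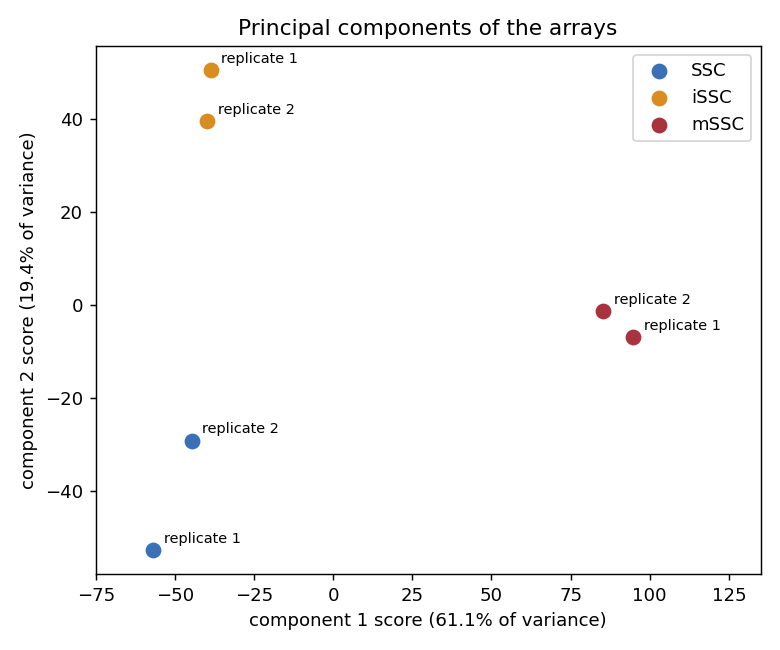
Scores of the 6 arrays on principal components 1 (horizontal axis, 61.1% of the variance) and 2 (vertical axis, 19.4%), with 1 point per array coloured by kind of cell. The mSSC arrays lie apart from the SSC and iSSC arrays along component 1.

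The comparison of mSSC with SSC asks which transcripts differ between the multipotent and the unipotent cells. Genes of the pluripotency network, which keeps embryonic stem cells undifferentiated, were far higher in mSSC. Nanog, a homeodomain factor of that network, rose by 8.66 ± 0.33 (n = 2 arrays per group) from a level of 3.35 near background in SSC, and Tdgf1, a co-receptor for Nodal, by 8.55 ± 0.30 from 3.88. Of the 22 measured core pluripotency genes 20 rose and 2 did not pass the test, and 21 rose when adjusted over the list alone. Sox2 rose by 5.22 ± 0.46, L1td1 by 6.94 ± 0.28 and Mybl2 by 3.95 ± 0.20. Pou5f1, which encodes Oct4, was already well above the array median in SSC and rose 12.8-fold (3.68 ± 0.44). Naive pluripotency genes followed, with 22 of 29 higher and 2 lower, or 24 and 2 when adjusted over the list alone. Among them were Esrrb (6.29 ± 0.25), the secreted factors Lefty2 (5.70 ± 0.23) and Fgf4 (3.50 ± 0.23), and Nr0b1 (7.12 ± 0.42). The median change was 3.88 in the core list (camera adjusted p = 3.1e-16) and 2.97 in the naive list (adjusted p = 4.9e-13). These became adjusted p = 0.13 and adjusted p = 0.43 with an estimated correlation. Klf4, another factor of the network, was at 0.62 ± 0.23 (adjusted p = 0.12), and Fgf5, a marker of later epiblast, was at 0.22 ± 0.22 (adjusted p = 0.54).

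Genes of the germ line were lower in mSSC. Zbtb16, which encodes the stem cell factor Plzf, fell 41.9-fold (-5.39 ± 0.55). Gfra1 and Ret, which together form the receptor for the niche factor Gdnf, changed by -4.27 ± 0.31 and -2.80 ± 0.24. In the list of germ line and piRNA genes 19 of 36 fell, 4 rose and 13 did not pass, against 22 and 5 when adjusted over the list alone. Dazl, an RNA-binding protein of germ cells, fell by 3.63 ± 0.36, and Bnc1 and Stk31 changed by -5.90 ± 0.48 and -4.99 ± 0.45. The list median was -1.92 (camera adjusted p = 4.0e-06; adjusted p = 0.43 with an estimated correlation). Of 31 meiosis genes 10 fell and 1 rose, or 16 and 2 adjusted over the list alone. Among them Sycp2, a part of the synaptonemal complex, changed by -4.56 ± 0.47 and Terb1, which tethers telomeres to the nuclear envelope, by -3.08 ± 0.25. Their median was -0.96 (adjusted p = 0.00017; adjusted p = 0.53 with an estimated correlation). Targets of Gdnf and Fgf signalling included 10 that fell and 2 that rose among 26, or 11 and 2 adjusted over the list alone. Lhx1 (-1.89 ± 0.20) and Cxcr4 (-2.64 ± 0.40) were among the lower, whereas Etv5 (1.92 ± 0.24) and Etv4 (1.33 ± 0.20) were higher. The median of that list was -0.90 (adjusted p = 0.013; adjusted p = 0.55 with an estimated correlation), and without mSSC replicate 1 it was -0.25 (adjusted p = 0.17). With members of other lists left out, 13 of the 26, it was -0.18 (adjusted p = 0.39). Among the brighter genes only, this list had adjusted p = 0.081 and the meiosis list adjusted p = 0.12.

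The list of undifferentiated spermatogonia was not called against other genes by camera, while fry called it lower (adjusted p = 0.011). Of its 37 members 9 rose, 14 fell and 14 did not pass, or 11 and 16 adjusted over the list alone (camera adjusted p = 0.25, median -0.57). The lower members included Glis3 (-4.08 ± 0.22) and Id4 (-1.36 ± 0.26). The higher ones included Utf1 (3.83 ± 0.29) and Cdh1 (5.69 ± 0.34), which pluripotent cells also express, and 18 of the 37 members belong to another list as well. Genes of differentiating spermatogonia had 5 lower and 2 higher members among 20, or 6 and 2 adjusted over the list alone (adjusted p = 0.37). Sohlh1, a transcription factor of spermatogonial differentiation, changed by -4.80 ± 0.42 and Tex101 by -4.50 ± 0.35. Stra8, which responds to retinoic acid before meiosis, was at -3.60 ± 1.26 (adjusted p = 0.10). Retinoic acid response genes had 5 lower and 1 higher among 22, or 10 and 2 adjusted over the list alone, among them Hoxb4 (-2.58 ± 0.27). Their median was -1.01 (adjusted p = 0.016; adjusted p = 0.43 with an estimated correlation). Without SSC replicate 2 the adjusted p of the retinoic acid list was 0.066, and without mSSC replicate 1 it was 0.087.

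Transcripts of macrophages, fibroblasts and Sertoli cells fell along with the germ line, and other somatic lists were not called. Of 20 macrophage genes 17 fell and 1 rose, with the same counts adjusted over the list alone, at a median of -5.09. Lyz2, a lysozyme of macrophages, fell 266-fold (-8.06 ± 0.30), and C1qb, a chain of complement component C1q, changed by -8.17 ± 0.35. The median level of the macrophage genes was 11.60 and 10.90 in the SSC arrays, 9.13 and 8.64 in the iSSC arrays, and 5.25 and 5.35 in the mSSC arrays. Of 38 fibroblast genes 24 fell and 14 did not pass, or 32 fell adjusted over the list alone. The collagen genes Col6a2 (-4.73 ± 0.41) and Col6a1 (-5.06 ± 0.60) were among them. The median level of the fibroblast genes was 7.45 in mSSC replicate 1 and 9.84 in replicate 2, against 12.16 and 11.49 in the SSC arrays. Of 24 Sertoli cell genes 11 fell and 2 rose, or 14 and 2 adjusted over the list alone. Aldh1a1, an enzyme of retinoic acid synthesis, changed by -8.51 ± 0.50 to a level of 3.83 near background, whereas the homeobox gene Rhox5 rose by 7.46 ± 0.26. Of 22 mesenchymal transition genes 14 fell, or 15 adjusted over the list alone, with Cdh2 at -4.50 ± 0.41 and Tgfbr2 at -4.39 ± 0.74 (with this sign in 2 of 3 probe sets), and 10 of these 22 belong to another list. The camera adjusted p was 5.5e-14 for macrophage, 1.2e-13 for fibroblast, 1.1e-05 for Sertoli cell and 1.8e-08 for mesenchymal transition genes. They were adjusted p = 0.43, adjusted p = 0.53, adjusted p = 0.27 and adjusted p = 0.43 with an estimated correlation. Leydig cell genes had a median of -0.20 (adjusted p = 0.25) with no called member among 13. Peritubular smooth muscle genes had 4 lower among 14, or 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.10), and endothelial genes 3 higher and 2 lower among 16, or 5 and 3 adjusted over the list alone (adjusted p = 0.67).

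Proliferation and glycolysis genes were higher in mSSC. Of 34 G2/M genes 12 rose and none fell, also when adjusted over the list alone, among them Cdk1 (1.83 ± 0.21), the kinase that drives mitosis, and Aurka (1.86 ± 0.24). Of 32 G1/S genes 9 rose, or 14 with 1 lower when adjusted over the list alone, among them the replication factor Gins2 (2.55 ± 0.21). Of 20 glycolysis genes 8 rose, or 12 adjusted over the list alone, led by the glucose transporter Slc2a3 (4.23 ± 0.41) and with hexokinase Hk2 at 1.34 ± 0.21. The medians were 0.82, 0.79 and 1.12, with camera adjusted p of 4.6e-06, 0.00017 and 4.6e-06. These lists had adjusted p = 0.53, adjusted p = 0.56 and adjusted p = 0.53 with an estimated correlation. Epithelial junction genes had 13 higher and 2 lower among 29, or 17 and 3 adjusted over the list alone, including Cldn6 (4.06 ± 0.23) and Cldn7 (4.58 ± 0.38). Their median was 1.39 (adjusted p = 1.0e-05; adjusted p = 0.43 with an estimated correlation). The DNA methylation list had 6 higher and 2 lower among 18, or 8 and 2 adjusted over the list alone (adjusted p = 0.0047; adjusted p = 0.43 with an estimated correlation). Tet1, which oxidises 5-methylcytosine, rose by 7.28 ± 0.22, Dnmt3l, a cofactor of the de novo methyltransferases, rose by 6.49 ± 0.45, and Mbd2 fell by 2.00 ± 0.24. With members of other lists left out, the DNA methylation median went from 0.74 to 0.19 (adjusted p = 0.31). Among the brighter genes only, this list had adjusted p = 0.070 and the epithelial list adjusted p = 0.055. All of these moved between the same samples as the macrophage and fibroblast genes.

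The other lists called had at most 3 members past the threshold. Trophoblast genes had 3 higher among 20, and the same count adjusted over the list alone, including Tfap2c (4.40 ± 0.50). Their median was 0.38 (adjusted p = 0.020; adjusted p = 0.46 with an estimated correlation), and 0.29 (adjusted p = 0.21) with members of other lists left out. Oxidative phosphorylation had 1 higher among 36, Uqcrc2 (0.79 ± 0.20), and 0 adjusted over the list alone (limma). Its median was 0.40 (adjusted p = 0.025; adjusted p = 0.64 with an estimated correlation). It was 0.16 (adjusted p = 0.41) without SSC replicate 1 and 0.41 (adjusted p = 0.077) without mSSC replicate 2. It was 0.30 (adjusted p = 0.15) after quantile normalization, 0.34 (adjusted p = 0.11) with probe sets averaged and 0.30 (adjusted p = 0.14) with the gene length trend removed. MHC class I genes had 2 lower among 11, Tapbp (-1.95 ± 0.33) and Psmb10 (-1.90 ± 0.46), also when adjusted over the list alone. Their median was -0.74 (adjusted p = 0.025; adjusted p = 0.61 with an estimated correlation). It was -0.36 (adjusted p = 0.12) without SSC replicate 1 and -0.57 (adjusted p = 0.060) without mSSC replicate 1, and among the brighter genes the list had adjusted p = 0.058. Lists not called had camera adjusted p from 0.10 to 0.90. The interferon response (adjusted p = 0.00028), Wnt target (adjusted p = 0.042) and 2-cell-like lists (adjusted p = 0.046) passed as higher without mSSC replicate 1, and the peritubular list (adjusted p = 0.016) as lower without SSC replicate 2. Among the brighter genes the endoderm list passed as lower, with a median of -3.19 (adjusted p = 0.035) against 0.24 over all its members, and the interferon response list as higher (adjusted p = 0.044). Among the lists not called the median, the mean or the test of the endoderm, neuroectoderm, Bmp and Tgf-beta target, cholesterol synthesis, maternally expressed imprinted and stress response lists differed in sign.

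Over all genes 3425 of 18194 differed between mSSC and SSC in limma, 1495 higher and 1930 lower in mSSC, and 1131 of them by at least 4-fold. Of the 38 lists camera called 9 as higher and 9 as lower. With an estimated correlation it called 0, with 4 at an unadjusted p under 0.05. Fry called 13 lists, and 10 of these were among those that camera called. Fry did not call the G2/M (fry adjusted p = 0.055), G1/S (0.062), glycolysis (0.062) and fibroblast (0.064) lists. Nor did it call the meiosis (0.075), Gdnf and Fgf target (0.080), oxidative phosphorylation (0.11) and MHC class I (0.19) lists. Without SSC replicate 1 the gene count was 2146, without mSSC replicate 1 it was 2116 and without either iSSC array it was 1966. An unmoderated test called 14 genes, with 4696 at an unadjusted p under 0.05.

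**Figure D2:**
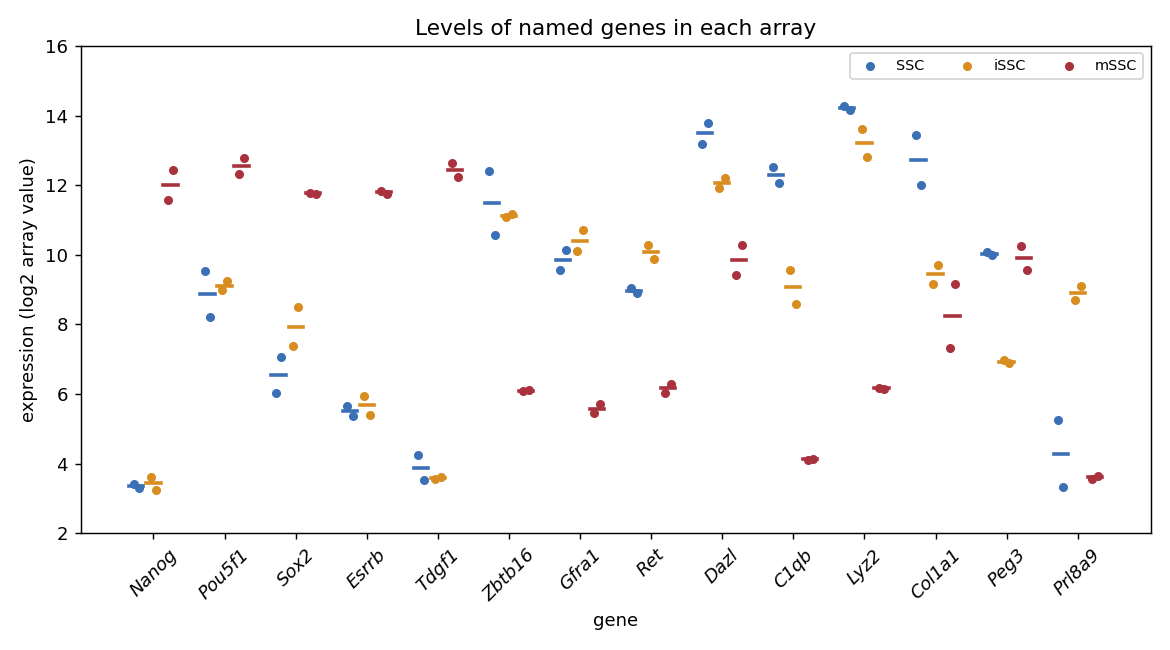
Levels of named genes (log2 array value, vertical axis) in each of the 6 arrays, with 1 point per array, a short line at the mean of the 2 arrays of a kind, and kinds told apart by colour. Nanog was 8.66 higher in mSSC than in SSC, while Peg3 stood at 6.92 in iSSC against 10.04 in SSC and 9.91 in mSSC.

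The comparison of iSSC with SSC asks what sets the intermediate state apart from the unipotent cells. Most of the genes called were lower in iSSC, among them transcripts of macrophages and other somatic cells, and pluripotency lists were not called. Arg1, an arginase of alternatively activated macrophages, fell 79.2-fold (-6.31 ± 0.98, n = 2 arrays per group, with an SD of 2.04 between the SSC arrays). F13a1, a coagulation factor made by macrophages, fell 31.8-fold (-4.99 ± 0.77, with an SD of 1.80 between the SSC arrays). Stab1, a scavenger receptor, fell 13.5-fold (-3.76 ± 0.46). The largest increases were in Prl8a9 and Prl8a2, members of the prolactin family, which rose by 4.63 ± 0.58 and 3.98 ± 0.68. Their SDs between the SSC arrays were 1.37 and 1.49, and Prl8a9 rose from 4.28 in SSC, a level near background.

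Of 20 macrophage genes 7 fell and 13 did not pass, or 13 fell adjusted over the list alone. C1qb fell 9.26-fold (-3.21 ± 0.35), C1qc 8.71-fold (-3.12 ± 0.39), and the leukocyte phosphatase Ptprc changed by -3.26 ± 0.44, although only 1 of its 2 probe sets had this sign. The list median was -1.71 (camera adjusted p = 1.5e-11; adjusted p = 0.62 with an estimated correlation). It was -1.27 (adjusted p = 2.5e-09) without SSC replicate 1, the array that held more macrophage signal. Of 38 fibroblast genes 2 fell, Timp3 (-3.04 ± 0.37) and Col6a2 (-2.65 ± 0.41), and 10 fell adjusted over the list alone. Col1a1 was at -3.29 ± 0.70 (adjusted p = 0.081). Sertoli cell genes had 3 lower among 24, or 6 adjusted over the list alone. These were Kitl, the ligand of Kit, which fell 5.62-fold (-2.49 ± 0.23), Cst12 (-3.35 ± 0.39) and the transcription factor Gata4 (-1.58 ± 0.23). The fibroblast list had a median of -0.74 (adjusted p = 1.1e-08; adjusted p = 0.62 with an estimated correlation) and the Sertoli list one of -0.92 (adjusted p = 6.9e-08; adjusted p = 0.30 with an estimated correlation).

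Among 14 peritubular smooth muscle genes 1 fell, the actin gene Actg2 (-2.61 ± 0.43), or 2 adjusted over the list alone, with a median of -0.61 (adjusted p = 0.021). Without SSC replicate 1 that median was -0.07 (adjusted p = 0.16), while it was -0.53 (adjusted p = 0.056) with members of other lists left out and -0.73 (adjusted p = 0.056) with the gene length trend removed. Mesenchymal transition genes had 0 changed among 22 in limma, or 1 higher and 4 lower adjusted over the list alone, with a median of -0.75 (adjusted p = 0.0019). Retinoic acid response genes had 0 changed among 22, or 1 lower adjusted over the list alone, with a median of -0.37 (adjusted p = 0.021). Each of these 3 lists had adjusted p = 0.62 with an estimated correlation. Without iSSC replicate 1 the retinoic acid median shrank to -0.13 (adjusted p = 0.23), and without SSC replicate 2 to -0.08 (adjusted p = 0.22). Meiosis genes had 3 lower among 31, or 4 adjusted over the list alone. These were Sycp2 (-3.76 ± 0.47), Terb1 (-2.62 ± 0.25) and the mismatch repair factor Mlh3 (-1.50 ± 0.23). The meiosis median was -0.01 and its mean -0.55 (adjusted p = 0.025; adjusted p = 0.62 with an estimated correlation). Without SSC replicate 2 the median was 0.21 (adjusted p = 0.97), and without iSSC replicate 2 it was 0.28 (adjusted p = 0.13). It was 0.24 (adjusted p = 0.75) among the brighter genes and -0.06 (adjusted p = 0.060) with the gene length trend removed. The median turned to 0.06 with arrays centred, to 0.03 after quantile normalization and to 0.06 with members of other lists left out, where the test still called the list lower.

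Spermatogonial stem cell genes tended upward as a list in iSSC, with few single genes past the threshold. Of 37 genes of undifferentiated spermatogonia 1 rose and 36 did not pass, or 7 rose adjusted over the list alone. Lhx1, a target of Gdnf signalling, rose 2.57-fold (1.36 ± 0.20). Etv5 was at 1.18 ± 0.24 (adjusted p = 0.077), Ret at 1.11 ± 0.24 (adjusted p = 0.081), Gfra1 at 0.56 ± 0.31 (adjusted p = 0.44) and Zbtb16 at -0.36 ± 0.55 (adjusted p = 0.81). The list median was 0.46 (adjusted p = 0.0018; adjusted p = 0.46 with an estimated correlation), and with members of other lists left out it was 0.10 (adjusted p = 0.42). Among 26 Gdnf and Fgf targets 1 rose, again Lhx1, or 5 adjusted over the list alone. Their median was 0.58 (adjusted p = 0.00069; adjusted p = 0.62 with an estimated correlation). These lists moved opposite to the macrophage and fibroblast genes in the same arrays.

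The pluripotency lists were not called with all genes and arrays. The core list had 0 of 22 genes changed in limma and a median of 0.31 (camera adjusted p = 0.095), and 0 were called adjusted over the list alone. Without iSSC replicate 1 the core list had a median of 0.28 and passed (adjusted p = 0.020), and among the brighter genes it had one of 0.34 and passed as well (adjusted p = 0.025). In the naive list 1 of 29 rose, Tcl1 (1.55 ± 0.27), also adjusted over the list alone, with a median of 0.15 (adjusted p = 0.73). Nanog was at 0.08 ± 0.33 (adjusted p = 0.94), Pou5f1 at 0.25 ± 0.44 (adjusted p = 0.84), Esrrb at 0.17 ± 0.25 (adjusted p = 0.81) and Sox2 at 1.38 ± 0.46 (adjusted p = 0.22).

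Several lists shifted upward by less than 1 on the log2 scale with at most 1 gene past the threshold. G1/S genes had a median of 0.61 (adjusted p = 0.0018), with 1 of 32 lower, Pola1 (-1.84 ± 0.24, with this sign in 1 of 2 probe sets), and 1 higher and 1 lower adjusted over the list alone. Without SSC replicate 1 the G1/S median was 0.34 (adjusted p = 0.17). Glycolysis genes had a median of 0.58 (adjusted p = 0.0055), with 0 of 20 called in limma and 5 higher adjusted over the list alone. Without SSC replicate 2 the glycolysis median was 0.33 (adjusted p = 0.15). Interferon response genes had a median of 0.70 (adjusted p = 0.021) and epithelial junction genes one of 0.42 (adjusted p = 0.021), each with 0 called over all genes and 0 adjusted over the list alone. Spermatid genes had a median of 0.31 (adjusted p = 0.031) with the same counts of 0. Without SSC replicate 2 the interferon median was 0.42 and the spermatid median 0.25, each with adjusted p = 0.22. Without iSSC replicate 1 the spermatid median was 0.14 (adjusted p = 0.52) and the epithelial median 0.23 (adjusted p = 0.16), and without SSC replicate 1 the epithelial median was 0.45 (adjusted p = 0.12). Stress response genes had a median of 0.48 (adjusted p = 0.025) and 1 higher gene among 26, also adjusted over the list alone. This was Nqo1, a quinone reductase of the oxidative stress response (2.99 ± 0.39), which rose 7.95-fold. Mesoderm genes had a median of 0.23 (adjusted p = 0.025) and 1 higher gene among 26, Lhx1, or 2 adjusted over the list alone. Without SSC replicate 2 the stress median was 0.35 (adjusted p = 0.15) and the mesoderm median 0.12 (adjusted p = 0.27), and without iSSC replicate 1 they were 0.30 (adjusted p = 0.082) and 0.15 (adjusted p = 0.079). With members of other lists left out the epithelial median was 0.34 (adjusted p = 0.073), the mesoderm median 0.21 (adjusted p = 0.092) and the interferon median 0.66 (adjusted p = 0.079). The stress median was 0.39 (adjusted p = 0.090) after quantile normalization. Removal of the gene length trend gave medians of 0.31 for the stress list and 0.08 for the mesoderm list, each with adjusted p = 0.060, and of 0.14 for the spermatid list (adjusted p = 0.11). Each list of this paragraph had adjusted p = 0.62 with an estimated correlation. All of them moved opposite to the macrophage, fibroblast and Sertoli lists in the same arrays.

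Over all genes 381 differed between iSSC and SSC in limma, 41 higher and 340 lower in iSSC, and 172 of them by at least 4-fold. Other genes with large increases were Glrx (2.80 ± 0.38), a glutaredoxin, Crct1 (2.80 ± 0.49), Sprr2d (2.50 ± 0.23), Plvap (2.19 ± 0.31), a protein of endothelial fenestrae, and the zinc transporter Slc39a4 (2.14 ± 0.26). Other large decreases were in Aspn (-4.44 ± 0.33), an extracellular matrix proteoglycan, Hs6st2 (-3.96 ± 0.37, with this sign in 3 of 4 probe sets), Pgm2l1 (-3.79 ± 0.64) and Defb19 (-3.59 ± 0.30). The groups did not overlap for 50.0% of genes, where 33.3% would be the share if the 4 values of each gene were in random order. Genes share variation between arrays, so this difference was not tested and does not by itself show a difference between the groups. Camera called 16 lists, 9 higher and 7 lower, and lists not called had adjusted p from 0.059 to 0.84. Without SSC replicate 1 the MHC class I (adjusted p = 0.0054) and Bmp and Tgf-beta target lists (adjusted p = 0.043) passed as higher, and those of differentiating spermatogonia (adjusted p = 0.023), germ line and piRNA (adjusted p = 0.024, although its median was 0.02) and G2/M (adjusted p = 0.034, with a median of -0.04 against 0.29) as lower. The MHC class I list also passed without iSSC replicate 2 (adjusted p = 0.012) and with probe sets averaged (adjusted p = 0.034), and oxidative phosphorylation without SSC replicate 2 (adjusted p = 0.0012), each as higher. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 2, the undifferentiated spermatogonia and Sertoli lists. The median, the mean or the test of the germ line and piRNA, neuroectoderm, G2/M, maternally expressed imprinted and Polycomb lists differed in sign.

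With a term for the replicate number limma called 148 genes, 125 of them among the 381. The count of 381 also rested on each of 3 arrays. Limma called 0 genes without SSC replicate 1 (2527 at an unadjusted p under 0.05), 0 without iSSC replicate 1 (1357) and 0 without iSSC replicate 2 (2000), and an unmoderated test called 2. Limma called 503 genes without SSC replicate 2, 147 higher and 356 lower, and 195 of these were among the 381. Averaging all probe sets of a gene gave 29 genes, testing every probe set 69, and testing for a change beyond 1.2-fold 203, and without SSC replicate 2 camera called 10 lists.

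**Figure D3:**
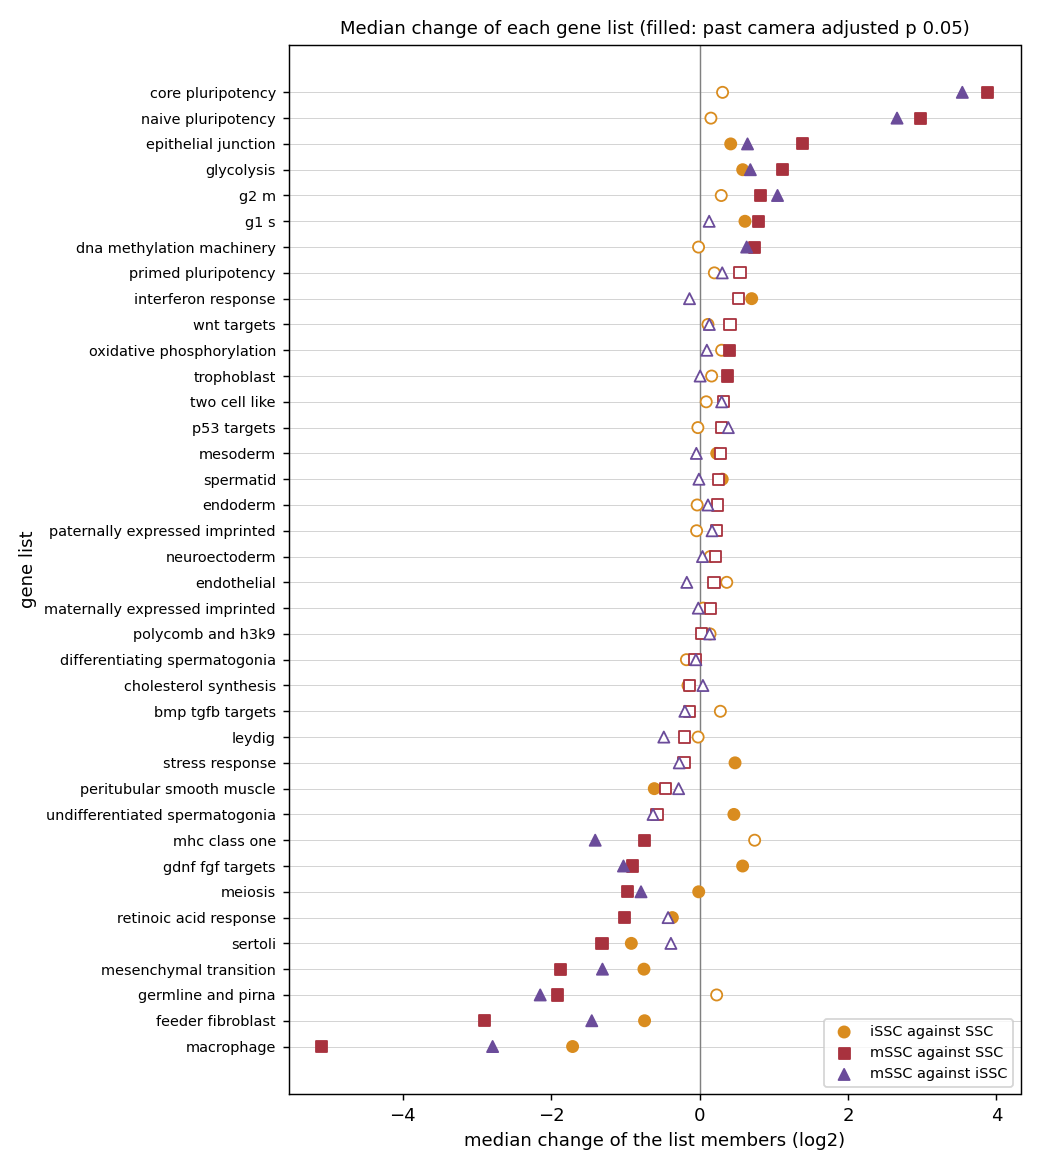
Median log2 change of the measured members of each of the 38 gene lists (horizontal axis) by list (vertical axis), with 1 marker per comparison and filled markers where camera passed an adjusted p of 0.05. Core pluripotency genes had medians of 3.88 and 3.54 in mSSC against SSC and iSSC and of 0.31 in iSSC against SSC, while macrophage genes had medians of -5.09, -2.79 and -1.71.

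The comparison of mSSC with iSSC asks what separates the multipotent from the intermediate state. Tdgf1 rose by 8.84 ± 0.30 (n = 2 arrays per group) and Nanog by 8.57 ± 0.33, from levels of 3.60 and 3.44 near background in iSSC. Mtm1, a phosphoinositide phosphatase, rose 309-fold (8.27 ± 0.42). Afp, the alpha-fetoprotein of fetal liver and yolk sac, changed by -8.51 ± 0.35 to a level of 3.68 near background in mSSC (with this sign in 4 of 5 probe sets), and the chemokine gene Ccl6 by -7.86 ± 0.40. Zic1, a zinc finger factor of neural development, changed by -6.88 ± 0.67. Core pluripotency genes had 17 higher among 22, or 21 adjusted over the list alone, with Pou5f1 up 10.8-fold (3.43 ± 0.44) and Sox2 up by 3.83 ± 0.46. Naive pluripotency genes had 22 higher and 2 lower among 29, with the same counts adjusted over the list alone, including Esrrb (6.13 ± 0.25) and Klf4 (1.27 ± 0.23). Their medians were 3.54 (camera adjusted p = 7.6e-17) and 2.66 (adjusted p = 1.7e-13), and with an estimated correlation they had adjusted p = 0.12 and adjusted p = 0.58.

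Germ line and piRNA genes had 22 lower and 5 higher among 36, or 24 and 7 adjusted over the list alone, with Bnc1 at -6.56 ± 0.48 and the Piwi protein gene Piwil4 at -3.25 ± 0.32. Their median was -2.15 (adjusted p = 6.3e-05; adjusted p = 0.61 with an estimated correlation). Gdnf and Fgf targets had 12 lower among 26, or 13 lower and 2 higher adjusted over the list alone, including Lhx1 (-3.25 ± 0.20), Pou3f1 (-2.34 ± 0.25) and Id4 (-2.40 ± 0.26). Their median was -1.02 (adjusted p = 6.3e-05; adjusted p = 0.61 with an estimated correlation). Genes of undifferentiated spermatogonia had 15 lower and 5 higher among 37, or 15 and 10 adjusted over the list alone, with a median of -0.63 (adjusted p = 0.066). Gfra1 fell 28.4-fold (-4.83 ± 0.31), Zbtb16 changed by -5.02 ± 0.55 and Ret by -3.92 ± 0.24. Without iSSC replicate 2 this list had adjusted p = 0.043, and without mSSC replicate 2 adjusted p = 0.045. It passed with probe sets averaged (adjusted p = 0.016) and in fry (adjusted p = 0.0025). Meiosis genes had 7 lower and 2 higher among 31, or 11 and 3 adjusted over the list alone, with Mei1 at -1.84 ± 0.30 and Mlh3 at 2.04 ± 0.23. Their median was -0.79 (adjusted p = 0.040; adjusted p = 0.72 with an estimated correlation), and it was -0.68 (adjusted p = 0.076) without iSSC replicate 1 and -0.48 (adjusted p = 0.15) without mSSC replicate 2. It was -1.05 (adjusted p = 0.23) among the brighter genes and -0.76 (adjusted p = 0.056) with members of other lists left out.

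Macrophage genes had 12 lower among 20, or 16 adjusted over the list alone, with Lyz2 at -7.05 ± 0.30 and the cathepsin gene Ctss at -5.74 ± 0.39, and fell in the same samples as the germ line genes. Fibroblast genes had 8 lower among 38, or 14 adjusted over the list alone, including Lgals1 (-2.32 ± 0.40). Mesenchymal transition genes had 6 lower among 22, or 8 adjusted over the list alone, including Foxc2 (-4.43 ± 0.43). MHC class I genes had 4 lower among 11, or 10 adjusted over the list alone, including H2-K1 (-1.35 ± 0.27), which presents peptides to T cells, and the immunoproteasome gene Psmb8 (-1.81 ± 0.43). The medians were -2.79, -1.45, -1.31 and -1.40, with camera adjusted p of 6.5e-09, 4.3e-06, 6.3e-05 and 0.00026. The fibroblast list had adjusted p = 0.72 with an estimated correlation and the other 3 adjusted p = 0.61.

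G2/M genes had 11 higher among 34, or 15 adjusted over the list alone, including Hmmr (3.31 ± 0.24) and the topoisomerase Top2a (1.59 ± 0.25). Epithelial junction genes had 11 higher and 3 lower among 29, or 13 and 4 adjusted over the list alone. E-cadherin, encoded by Cdh1, rose by 4.20 ± 0.34 and Marveld2, a tricellular junction protein, fell by 3.07 ± 0.27. Glycolysis genes had 4 higher and 1 lower among 20, also adjusted over the list alone, including Slc2a3 (2.78 ± 0.41) and, among the lower, Pfkfb3 (-1.81 ± 0.33). The DNA methylation list had 5 higher and 1 lower among 18, also adjusted over the list alone, including Tet1 (7.60 ± 0.22) and Dnmt3l (5.97 ± 0.45). The medians were 1.05, 0.65, 0.68 and 0.64, with camera adjusted p of 9.2e-07, 0.00044, 0.0025 and 0.00044. They had adjusted p = 0.61, adjusted p = 0.61, adjusted p = 0.72 and adjusted p = 0.49 with an estimated correlation. Without mSSC replicate 1 the glycolysis median was 0.33 (adjusted p = 0.061). Among the brighter genes the epithelial median was 0.34 (adjusted p = 0.35) and the DNA methylation list had adjusted p = 0.080, and with members of other lists left out the latter had adjusted p = 0.083.

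Over all genes 3117 differed between mSSC and iSSC in limma, 1370 higher and 1747 lower in mSSC, and 1040 of them by at least 4-fold. Camera called 13 lists, 6 higher and 7 lower, and lists not called had adjusted p from 0.066 to 0.99. Without iSSC replicate 2 the p53 target list (adjusted p = 0.020) passed as higher and the Leydig cell list (adjusted p = 0.046) as lower, and without mSSC replicate 1 the 2-cell-like list passed as higher (adjusted p = 0.019). The interferon response list passed as higher without mSSC replicate 1 (adjusted p = 0.020) and as lower without mSSC replicate 2 (adjusted p = 0.034). With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05. Fry called 8 lists, and 7 of these were among those that camera called. Fry did not call the fibroblast, glycolysis and meiosis lists (each with fry adjusted p = 0.24). Nor did it call the mesenchymal transition (0.12), MHC class I (0.10) and G2/M (0.098) lists. The median, the mean or the test of the endoderm, neuroectoderm, and Bmp and Tgf-beta target lists differed in sign. The gene count was 604 without iSSC replicate 1, 771 without iSSC replicate 2, 1954 without mSSC replicate 1 and 3724 without SSC replicate 1. An unmoderated test called 26 genes, with 4263 at an unadjusted p under 0.05.

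Because the labels call iSSC an intermediate state, its place between the other kinds was measured. Over the 3425 genes that differed between mSSC and SSC, the median position of iSSC was 0.21 on a scale where SSC is 0 and mSSC is 1, with quartiles of -0.01 and 0.48. The 2 iSSC arrays gave 0.236 and 0.190 (SD 0.033), and 76.5% of the genes lay below 0.5. Macrophage genes had a median of -1.71 in iSSC and -5.09 in mSSC against SSC, and Nanog was at 0.08 ± 0.33 and 8.66 ± 0.33. The 2 differences share the SSC arrays, and with these split the position was 0.0947 and 0.110. It was 0.378 without SSC replicate 2, and between 0.164 and 0.206 without any 1 of the other 5 arrays.

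A total of 199 genes lay outside the range of the other kinds in iSSC, 27 highest and 172 lowest there. The highest included Prl8a9, at 8.91 in iSSC against 4.28 in SSC and 3.60 in mSSC, Prl8a2, Crct1, Plvap, Glrx and Stx11 (2.10 ± 0.23 above SSC), which encodes a syntaxin. The lowest included Peg3, a paternally expressed imprinted zinc finger gene, which was 8.67-fold lower than in SSC (-3.12 ± 0.28). Relative to iSSC it was 7.95-fold higher in mSSC (2.99 ± 0.28), with a level of 6.92 in iSSC against 10.04 in SSC and 9.91 in mSSC. Diaph2, a formin that regulates actin, was at -2.85 ± 0.35 against SSC, Ccar1 at -2.91 ± 0.39, Stag2, a cohesin subunit, at -2.68 ± 0.29, Vamp7, a vesicle fusion protein, at -2.67 ± 0.21 (with this sign in 1 of 2 probe sets) and Zfp932 at -2.62 ± 0.44. Limma called 0 such genes without SSC replicate 1, without iSSC replicate 1 or without iSSC replicate 2, where 2527, 1357 and 2000 genes had an unadjusted p under 0.05 against SSC, and an unmoderated test called 2. The count was 72 with a term for the replicate number, 14 with all probe sets of a gene averaged, 38 with every probe set tested and 94 for changes beyond 1.2-fold.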

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

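The tests in this part were chosen after the results they bear on were seen, except the list tests with camera, an estimated correlation and fry, the calls of genes apart in iSSC, averaging of probe sets and leaving out SSC replicate 1, which were planned before.

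Probe sets outside the gene comparisons, because no single gene was tied to them, carried signal too. In limma 140 of these 10092 probe sets were higher in mSSC than in SSC and 190 were lower, and 149 were higher in mSSC than in iSSC and 109 lower. In iSSC against SSC 0 were higher and 3 were called, with 1118 at an unadjusted p under 0.05.

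The macrophage list was lower in iSSC than in SSC (adjusted p = 1.5e-11; adjusted p = 0.62 with an estimated correlation and 0.28 in fry; adjusted p = 2.5e-09 without SSC replicate 1). A smaller share of the same macrophages alone would lower every transcript by 1 ratio, if only macrophages made it and the array scale were linear. The test used the 12 members with a level between 8 and 13 in SSC and below 7 in mSSC. Their fall varied 9.47 times as much as between arrays, past the threshold of an F test. Adgre1 and Cd14, chosen after their values were seen, were at -0.11 ± 0.39 and -0.23 ± 0.80, and C1qb at -3.21 ± 0.35. Fibroblast genes were low in mSSC too (median -2.90 against SSC), so the filter cannot ensure that only macrophages made these transcripts. The test therefore cannot decide on a smaller share alone. SSC replicate 1 alone is argued against, since the list median without it was -1.27. A change in the kind or state of the macrophages may remain beside a change in their number, and was not tested. The biological difference between the kinds of cell also stays open.

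Of 199 genes apart in iSSC 172 were the lowest there. Their gene spans were longer, with a lower quartile of 30.7 kb against 7.82 kb for other genes. After the average trend on gene length was removed 160 genes were lowest, which argues against that average trend as the whole cause. Its removal moved the median change of all genes in iSSC against SSC only from 0.10 to 0.005. The test therefore cannot judge a length effect on some genes only. Faults of the chosen probe sets alone are argued against by the other probe sets of these genes, of which 82.6% were lower in iSSC than in both other kinds, against 27.6% for other genes, but these fell by a median of only 0.85 against SSC where the chosen ones fell by 1.91, and with probe sets averaged 13 genes were called lowest, so the size of the fall and the count may rest in part on the choice. Poorer RNA in the iSSC arrays cannot be told apart from other causes: the mean 3' minus 5' signal of the controls was 0.932 in iSSC, 1.17 in SSC and 0.913 in mSSC, within the spread of the arrays (SD 0.804 in SSC, where replicate 1 had the larger value for each of the 5 controls). A difference in the cells may account for the pattern and was not tested.

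The imprinted transcripts Meg3, Rian and Mirg were 3.12, 4.39 and 3.67 higher in mSSC replicate 2 than in replicate 1, and Rian and Mirg were chosen after their values were seen. Feeder fibroblasts are a possible source of such RNA, but in replicate 2 both Rian and Mirg were at least 2.16 above the highest SSC array, although its fibroblast median of 9.84 was below that of the SSC arrays, which argues against RNA as in those arrays. For Meg3, which was at -0.36 against the highest SSC array, a fibroblast source cannot be told apart from a difference in the cells. A difference common to arrays of 1 number is argued against, since the largest difference in SSC or iSSC was 1.198 in size and the smallest in mSSC was 3.12. With 1 array on each side the difference between the mSSC arrays was not tested.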

How the results depend on the processing

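Removal of the gene length trend and quantile normalization before the list tests were chosen after seeing the data. Of 39 named genes called in iSSC against SSC, 27 stayed called with both other scalings, as did 143 of 146 in mSSC against SSC and 139 of 141 in mSSC against iSSC. None of them changed direction in the 17 settings tried. With the unmoderated test left aside, 0, 115 and 74 of these stayed called in every setting. The signal of dim genes is limited by background, and with only the brighter genes 302, 2479 and 2375 genes were called. Each centring or quantile normalization kept the gene counts within 1.5 times.

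With a replicate block for the array numbers, which the labels do not say pair the samples, limma called 148 genes in iSSC against SSC (125 also without the block), 3428 in mSSC against SSC and 3175 in mSSC against iSSC, and 72 apart in iSSC. Of the named genes called, 19 of 39, 143 of 146 and 139 of 141 stayed called with the block. Deviations from the group means had r of 0.12, 0.0683 and 0.171 between pairs of groups.

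For iSSC against SSC, 381 genes became 29 with probe sets averaged, 69 with every probe set tested, 203 beyond 1.2-fold and 2 unmoderated, and the 199 genes apart became 14, 38, 94 and 2. For mSSC against SSC, 3425 became 1966 on 4 arrays and 14 unmoderated, and for mSSC against iSSC 3117 became 26 unmoderated. Leaving out 1 array gave 0 to 503, 1966 to 3462 and 604 to 3724 genes, 0 to 220 apart, and positions from 0.164 to 0.378, while splitting the SSC arrays gave 0.0947 and 0.110. The 16, 18 and 13 lists called became 0, 0 and 0 with an estimated correlation (2, 4 and 3 at an unadjusted p under 0.05, camera). Fry called 2, 13 and 8, of which 2, 10 and 7 were among the lists called by camera. Over all settings, and apart from the 2 reversals below, single lists lost a call 57, 44 and 27 times and gained 1 in 11, 9 and 8. Leaving out 1 array gave 10 to 18, 16 to 18 and 12 to 16 lists. Without SSC replicate 2 the meiosis list in iSSC against SSC reversed to a median of 0.21 (range -0.43 to 0.28 over the arrays left out), and without mSSC replicate 1 the interferon list in mSSC against iSSC reversed to 0.37 (range -0.61 to 0.37). The 4-array fits and leaving out arrays use fewer samples. The estimated correlation is tested on 3 degrees of freedom, and its median over the lists was 0.14 against the preset of 0.01. For the other changes the cause was not tested.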

Other observations

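Values in this part were looked up after the results were seen, except those of the planned gene lists and the fixed panel.

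Single genes of the imprinted lists, which many tissues express from 1 parental copy, moved in both directions. The parental copies were not told apart here. Paternally expressed imprinted genes had 5 higher and 5 lower among 23 in mSSC against SSC, with the same counts adjusted over the list alone (camera adjusted p = 0.82). Igf2, a fetal growth factor, changed by -3.58 ± 0.55 and Ndn by -2.01 ± 0.23 (with this sign in 6 of 8 probe sets), while Slc38a4 rose by 1.70 ± 0.26. Maternally expressed imprinted genes had 1 higher, Phlda2 (3.12 ± 0.24), and 4 lower among 25, with the same counts adjusted over the list alone, including Cdkn1c (-2.54 ± 0.25), a cell cycle inhibitor (adjusted p = 0.51). In iSSC against SSC, Peg3 fell, and so did 2 genes of the maternally expressed list, Ube3a (-2.88 ± 0.48), a ubiquitin ligase, and Ppp1r9a (-1.84 ± 0.32). Whether these genes are imprinted in these cells was not tested.

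Single lineage genes differed between mSSC and SSC, in lists that were not called. Endoderm genes had 6 higher and 7 lower among 25, or 8 and 8 adjusted over the list alone (adjusted p = 0.90), with Afp at -7.01 ± 0.35. Neuroectoderm genes had 2 higher and 6 lower among 26, also adjusted over the list alone (adjusted p = 0.90), with Hoxb2 at -3.11 ± 0.29 and Zic1 at -5.57 ± 0.67. Mesoderm genes had 3 higher and 3 lower among 26, also adjusted over the list alone (adjusted p = 0.37), with Bmp4 at 3.34 ± 0.39 and Foxf1 at -2.88 ± 0.41. The primed pluripotency genes Nodal (5.13 ± 0.28) and Otx2 (5.88 ± 0.54) rose, in a list with 7 higher and 5 lower among 23, also adjusted over the list alone (adjusted p = 0.17 by camera and 0.042 by fry). These genes moved in the same samples as the macrophage and fibroblast genes.

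The Y-linked gene Uba1y, an activating enzyme for ubiquitin, was lower in mSSC than in SSC (-3.91 ± 0.32, adjusted p = 0.0014), Usp9y was at -3.09 ± 0.44 (adjusted p = 0.0074) and Zfy2 at -1.91 ± 0.39 (adjusted p = 0.021). In mSSC against iSSC limma called Uba1y lower (-4.48, adjusted p = 0.0013). It did not call Usp9y (-0.67, adjusted p = 0.38) or Zfy2 (-0.12, adjusted p = 0.89) there. Eif2s3y, also Y-linked, was at -0.19 ± 0.30 in mSSC against SSC (adjusted p = 0.70), at levels from 8.31 to 9.62 in all 6 arrays. Slc7a11, a cystine transporter, was at 2.08 ± 0.31 in iSSC against SSC (adjusted p = 0.036), and its SSC levels of 4.00 and 4.24 were near background. Looked up with it, Cbr3 was at 1.71 ± 0.30 (adjusted p = 0.048) and Gclm at -0.10 ± 0.24 (adjusted p = 0.89).

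The genes called lower in iSSC against SSC and those called lower in mSSC against SSC shared 162 genes, where independent lists would share 36.1. The 2 comparisons use the same SSC arrays, so shared genes are not independent evidence. The correlation of the log2 changes across genes was 0.38, against 0.50 in simulations without any change. The shared SSC arrays alone set that 0.50, and changes in either comparison alter the correlation, so it cannot tell shared change from none. The covariance of the log2 changes was 0.269, against 0.0755 in these simulations.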
